A study of Mus musculus with 18 samples.

How the data were processed

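Total RNA of mouse C57BL6/J bone marrow-derived macrophages was measured after 7 days in 20% L929-conditioned medium and 80% DMEM, with stranded TruSeq libraries, per the labels. Raw counts per gene were deposited, made by the authors with STAR, HTSeq and mm10 per the submitters' processing notes; their versions are not given in the sources used here. The strand setting of HTSeq is not given in the sources used here either, so genes that overlap others are less certain. Of 312 named genes matched to GENCODE vM21 (GRCm38), 57 overlap another gene on the same strand and 99 on the other strand. Reads shared between close paralogs such as Ifit3 and Ifit3b were not analysed here.

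Both tables held 23052 gene symbols. The endotoxin-tolerant table had 17516 genes with a count above 0 and 12492 tested, and in the stimulation data these were 16715 and 12506, after edgeR's filterByExpr. Libraries detected 14648 to 15299 genes in the tolerant set and 14310 to 14988 in the stimulation set. The 10 most abundant genes took 11.1 to 14.9% and 7.51 to 11.6% of counts. TMM factors ran from 0.957 to 1.03 in the tolerant set, and averaged 0.806 with LPS, 1.10 untreated and 1.12 with IL-4. Replicates were not copies of each other: 21 pairs had chi-square values of 7.93 to 180 per degree of freedom.

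Each table was fitted on its own with all its groups in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM and the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 0.271 in the tolerant set (0.124 with the replicate block) and 0.174 in the stimulation set. Residual degrees of freedom were 9 and 3. Standard errors are those of the log2 fold change. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

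Replicate numbers were checked as pairs by correlating deviations from group means. In the tolerant set all 12 same-number pairs were positive (0.501 to 0.823). The difference of replicates 1 and 2 from 3 and 4 alone makes them so. Within replicates 1 and 2 the same-number correlations were 0.15, 0.05 and -0.01, and within 3 and 4 they were 0.54, -0.40 and -0.48. So the numbers did not consistently pair the samples, but a block on them also takes out that difference. A block fit is given beside results it changes. The labels do not say what the numbers mark. Libraries of the same batch with another number correlated as well (0.465 to 0.836), and across batches the values were -0.838 to -0.567. Here a batch means replicates 1 and 2, or 3 and 4, a grouping seen in the data. Within a batch each group has 2 libraries, and lists were tested there with camera at the preset correlation only. Those p-values set the list genes against the other genes in that batch and do not measure the spread between libraries.

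The named genes followed a rule written before the data were examined: the 10 largest rises and falls per comparison (5 for AKG against glutamine and for IL-4 against LPS) among called genes with a mean log2 CPM of at least 2 and no overlap between groups. To these came the 4 members with the smallest p of each list, and Tnf, Il1b, Il6, Arg1, Retnla, Chil3, Mrc1, Asns and Glul. Of the genes this rule gave, 2 are not reported here. A group at 0 counts was set to 3 counts to give a least fold, and groups with 1 to 3 counts got a count ratio with a 95% interval.

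Gene lists, 26 in all, were fixed in advance and tested with camera at a preset inter-gene correlation of 0.01, with p adjusted over the lists. Correlations estimated per list and fry were the alternatives. Stimulation genes were moved to the tolerant set as lists of 50 out of 499 (IL-4) and 1278 (LPS) genes that met the rule. Shared controls were handled by simulating counts with no effect and by splitting the shared libraries.

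Tested on simulated data with the spread of these libraries, the tolerant design recovered 36.4, 68.7 and 89.4% of changes of 1.5, 2 and 4 fold (65.2, 83.6 and 97.0% with the block; 12444 genes in step). The stimulation design recovered 2.99, 45.5 and 86.2% (12347 genes in step). False calls were 0% of calls in the tolerant design (2.69% with the block) and 12% in the stimulation design. With no effect there were 0 calls in both. Yet only 1.41% of p-values were under 0.05 in the tolerant design without the block (4.71% with it), so that fit calls too few genes. Over changes of 1.5, 2 and 4 fold pooled, DESeq2 1.42.0 recovered 72.9 and 61.1%, and limma-voom 63.8 and 44.4%. These are not to be set against the values per fold, and their false calls were not counted. A changed gene set was found (adjusted p = 4.5e-33 and 7.0e-15) and an unchanged set was not (0.54 and 0.68).

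Alternatives were RLE size factors, no filter, a filter of 1 CPM, DESeq2, limma-voom, each pair of groups alone, the replicate block and each library left out. Added after seeing the data were the batch as a factor, each batch alone, a crossed block in the stimulation set, the untreated libraries split between IL-4 and LPS, and the estimated correlation together with the block.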

Results

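RNA sequencing counts covered 18 libraries of mouse bone marrow-derived macrophages. In the endotoxin-tolerant set (12 libraries), cells were kept with glutamine, without glutamine, or without glutamine but with α-ketoglutarate (AKG), 4 libraries each. In the stimulation set (6 libraries), cells were untreated or given IL-4 or LPS for 6 h, 2 libraries each. Library totals ran from 28.3 to 37.8 M counts in the tolerant set and from 34.2 to 39.8 M in the stimulation set. The group without glutamine was sequenced less deeply (mean 30.5 M) than the groups with glutamine (35.7 M) and with AKG (35.6 M). The labels do not say that replicates are separate animals or cultures, so the p-values of single genes measure only the spread between these samples. Camera p-values of lists set list genes against other genes, at a preset or an estimated correlation.

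Replicate numbers 1 and 2 differed from 3 and 4 in every tolerant group. The first principal component held 59.2% of the variance and separated these replicates, and the second held 19.6% and separated the groups. Stromal fibroblast markers had a median log2 difference of 2.09 in replicates 3 and 4 over 1 and 2 (8 higher genes). For NRF2 targets the difference was 1.15 (12 higher genes), for ATF4 targets 0.58 (20 higher, 2 lower), for interferon response genes -0.46 (19 lower) and for MHC class II genes -0.75 (9 lower). This structure entered every tolerant comparison, so each is given without and with the replicate number as a block.

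**Figure D1:**
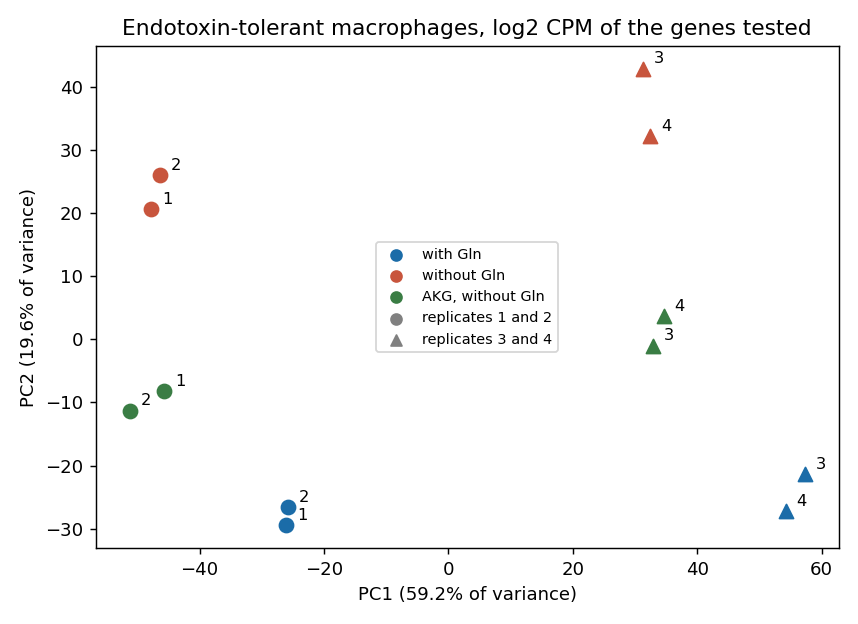
Principal components of log2 CPM in the 12 endotoxin-tolerant libraries; each point is a library and its number is the replicate. PC1 (59.2%) separates replicates 1 and 2 from 3 and 4, and PC2 (19.6%) separates the groups.

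Which transcripts depended on glutamine in tolerant macrophages was asked first, with 4 libraries per group. edgeR's quasi-likelihood test called 587 of 12492 genes (287 higher and 300 lower without glutamine), and 2707 with the replicate block (1084 higher, 1623 lower), among them all 587. Without replicate 2 of the group without glutamine the count fell to 229, and the 2 groups alone gave 243. Changes above 1 log2 unit numbered 74 upward and 187 downward, and 153 and 658 with the block. Group values did not overlap in 1543 genes (12.4%), against 2.86% by chance if the batch is ignored.

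Cells short of amino acids switch on ATF4 targets, and Trib3 (chr2:152337422-152344032, minus strand) had the largest rise among called genes with a mean log2 CPM of at least 2. Its mean was 28.7 CPM without and 4.32 CPM with glutamine, a log2 fold change of 2.73 (SE 0.39, adjusted p = 0.0061). Ddit3 rose by 1.12 (SE 0.13, adjusted p = 0.0030) and Mthfd2 by 1.18 (SE 0.26, adjusted p = 0.028). Slc7a1 had 1.41 (SE 0.37, adjusted p = 0.056; 0.0040 with the replicate block) and Asns 1.20 (SE 0.43, adjusted p = 0.16; 0.0098 with the block). In the ATF4 list 3 of 25 genes rose (7 rose and 1 fell adjusted over the list alone; 11 rose and 4 fell with the block). Its median was 0.27 (camera adjusted p = 8.3e-05, adjusted p = 0.60 with an estimated correlation), 0.57 within replicates 1 and 2 and 0.23 within 3 and 4.

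Aminoacyl-tRNA synthetase genes, many of them ATF4 targets, included some that rose. Sars rose by 0.58 (SE 0.10, adjusted p = 0.011), Yars by 0.54 (SE 0.13, adjusted p = 0.037) and Aars by 0.76 (SE 0.19, adjusted p = 0.049). Of 20 genes 3 rose (6 adjusted over the list alone; 11 with the replicate block), median 0.19 (adjusted p = 8.7e-05, adjusted p = 0.56 with an estimated correlation). Glul (chr1:153899944-153909723, plus strand), which makes glutamine, fell by 0.58 (SE 0.08, adjusted p = 0.0052). The glutamine carrier gene Slc38a1 rose by 0.54 (SE 0.08, adjusted p = 0.0067). The other 15 of the 17 glutamine use and transport genes did not pass, and the list median was 0.06 (adjusted p = 0.47).

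Endotoxin tolerance holds down cytokine genes, and several of these were higher without glutamine. Acod1 rose by 1.53 (SE 0.23, adjusted p = 0.0077), Il1a by 2.65 (SE 0.48, adjusted p = 0.013) and Cxcl1 by 1.98 (SE 0.42, adjusted p = 0.023). Il6 (chr5:30013114-30019981, plus strand) rose from 0.349 to 2.74 CPM, a log2 fold change of 2.95 (SE 0.69, adjusted p = 0.035). Tnf had 0.43 (SE 0.49, adjusted p = 0.75; 0.49, adjusted p = 0.030 with the replicate block) and Il1b 1.10 (SE 0.80, adjusted p = 0.56; 0.69, adjusted p = 0.16 with the block). In the inflammatory list 5 of 22 genes rose (5 adjusted over the list alone; 7 rose and 1 fell with the block). The median was 0.36 (adjusted p = 0.00031, adjusted p = 0.17 with an estimated correlation), 0.31 within replicates 1 and 2 and 0.22 within 3 and 4.

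Some antimicrobial genes described as spared by tolerance also rose. Clec4e (chr6:123281789-123289870, minus strand) rose by 1.70 (SE 0.18, adjusted p = 0.0017), F10 by 1.75 (SE 0.26, adjusted p = 0.0067) and Lcn2 by 1.17 (SE 0.24, adjusted p = 0.020). Of 14 genes 3 rose (5 adjusted over the list alone; 9 rose and 1 fell with the replicate block), median 0.62 (adjusted p = 3.3e-07, adjusted p = 0.051 with an estimated correlation). Among negative regulators of TLR signalling 3 of 22 rose: Cd274 by 0.73 (SE 0.12, adjusted p = 0.0087), Tollip by 0.41 (SE 0.07, adjusted p = 0.0095) and Tnip1 by 0.49 (SE 0.10, adjusted p = 0.017). Adjusted over the list alone 8 rose and 2 fell, and with the block 8 rose and 4 fell. The median of 0.24 had adjusted p = 0.00052 (0.053 with the replicate block, adjusted p = 0.49 with an estimated correlation). Interferon response genes had a median of -0.25 with 0 of 30 called (adjusted p = 0.0097; 0.076 and 2 lower genes with the block, adjusted p = 0.83 with an estimated correlation). That shift came from replicates 1 and 2, where the median was -0.56 with 20 lower genes and 1 higher, while replicates 3 and 4 gave 0.08.

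Among called genes with a mean log2 CPM of at least 2, Dkk3 (chr7:112116017-112159057, minus strand) fell most, by 4.76 (SE 0.81, adjusted p = 0.010), from 17.5 to 0.646 CPM. Col1a1 (chr11:94936224-94953042, plus strand) fell by 4.35 (SE 0.86, adjusted p = 0.017) and Col6a3 by 4.18 (SE 0.83, adjusted p = 0.018). Actg2, Postn, Loxl2, Acta2 and Wisp2 fell by 3.97, 3.70, 3.45, 3.26 and 3.17 (adjusted p = 0.020, 0.045, 0.049, 0.030 and 0.027). In the stromal marker list 3 of 8 genes fell (6 adjusted over the list alone; all 8 with the replicate block), median -2.97. Its adjusted p was 1.0e-06 (adjusted p = 0.49 with an estimated correlation, 0.015 with that and the block). The fall was as large within replicates 1 and 2 (-2.93) as within 3 and 4 (-2.88). Of the 300 lower genes 135 (45%) were also higher in replicates 3 and 4, against 88.8 expected of independent lists, and of the 287 higher genes 54 (18.8%, 84.9 expected). With the block these were 757 of 1623 lower genes (46.6%, 480 expected) and 503 of 1084 higher genes (46.4%, 321 expected). That overlap is thus not particular to falls.

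Of the cell cycle genes some fell as well. Plk1 (chr7:122159439-122169873, plus strand) fell by 3.07 (SE 0.48, adjusted p = 0.0081), Birc5 by 2.50 (SE 0.42, adjusted p = 0.0095), Top2a by 1.96 (SE 0.32, adjusted p = 0.0087) and Cdk1 by 1.02 (SE 0.18, adjusted p = 0.010). Of 22 genes 11 fell (15 adjusted over the list alone; 15 with the replicate block), median -1.07 (adjusted p = 6.9e-15, adjusted p = 0.17 with an estimated correlation). The within-batch medians were -0.45 in replicates 1 and 2 and -1.47 in 3 and 4. For Top2a the fall differed between these batches by 1.76 log2 units (SE 0.30, adjusted p = 0.022 for the interaction). Histone transcripts, a sign of dividing cells or of poly-A loss, moved the other way, at 0.0263% of counts without glutamine, 0.0175% with it and 0.0208% with AKG.

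**Figure D2:**
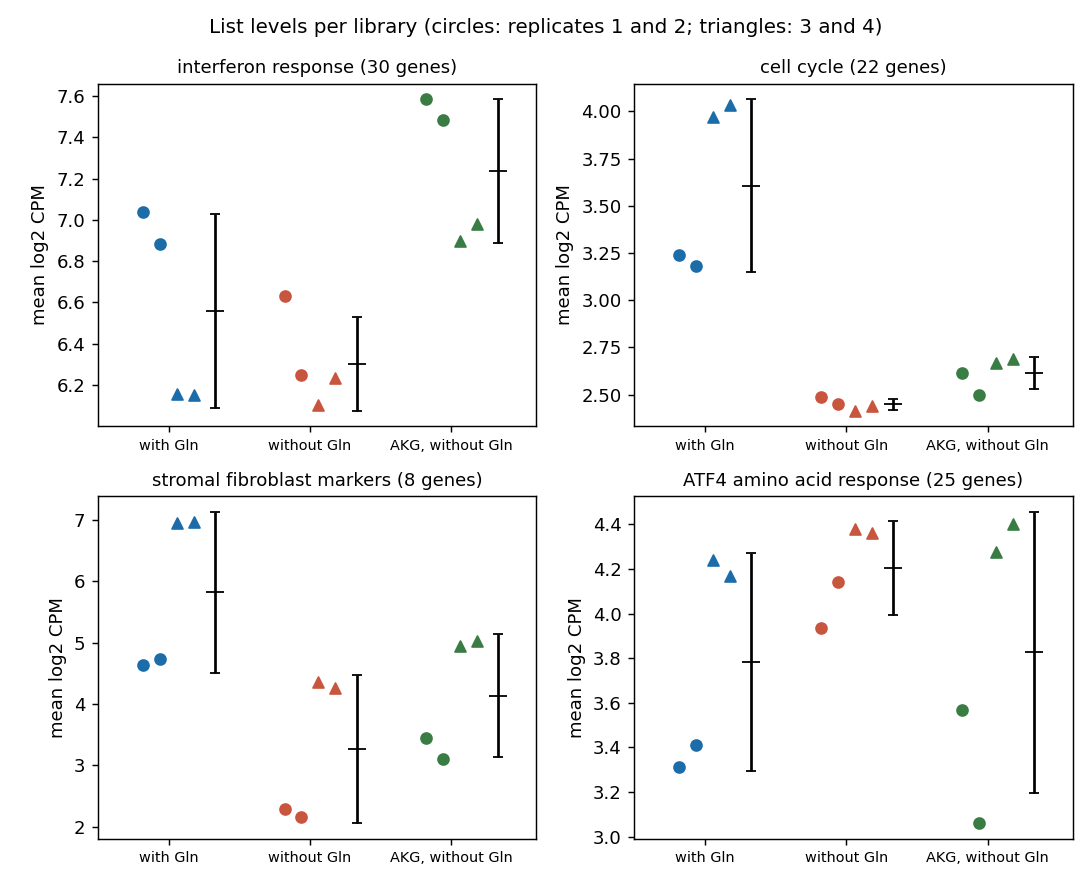
Mean log2 CPM of 4 gene lists per endotoxin-tolerant library; points are libraries and bars are the mean with its SD. Stromal and cell cycle lists are lowest without glutamine, and the interferon list is highest with AKG.

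Other rises were Acsl1 (1.76, SE 0.27, adjusted p = 0.0081), Vwf (1.88, SE 0.30, adjusted p = 0.0087), Plcxd2 (1.91, SE 0.45, adjusted p = 0.037) and Stra6l (1.62, SE 0.12, adjusted p = 0.00014). Smpdl3b rose by 1.67 (SE 0.35, adjusted p = 0.022) and Slc43a3 by 1.61 (SE 0.33, adjusted p = 0.021). In the glycolysis and hypoxia list Vegfa rose by 0.97 (SE 0.23, adjusted p = 0.037) and the other 20 genes did not pass (3 rose adjusted over the list alone; 5 rose with the replicate block). Its median was 0.15 (adjusted p = 0.0010, adjusted p = 0.56 with an estimated correlation), 0.35 within replicates 1 and 2 and 0.04 within 3 and 4. Among cholesterol synthesis genes Dhcr7 fell by 0.37 (SE 0.09, adjusted p = 0.047), 1 of 21 (4 adjusted over the list alone; 7 with the block). The median of -0.36 had adjusted p = 0.00093 (adjusted p = 0.60 with an estimated correlation), and was -0.03 within replicates 1 and 2 and -0.48 within 3 and 4. In the lysosome list Mcoln1 and Atp6v0d1 rose by 0.27 and 0.29 (SE 0.06 and 0.07, adjusted p = 0.025 and 0.031), 2 of 18 genes (5 with the block). That list's median was 0.07 (adjusted p = 0.043, adjusted p = 0.49 with an estimated correlation). Replicate 3 without glutamine stood apart on this score, and without it adjusted p = 0.19 (median 0.09).

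Remaining lists did not pass without the block. Mrc1 had -1.07 (SE 0.54, adjusted p = 0.34; -1.18, adjusted p = 0.00056 with the replicate block) and Arg1 -0.07 (SE 0.42, adjusted p = 0.96); the IL-4 list had a median of 0.09 and a mean of -0.05 (adjusted p = 0.71). Cd86 rose by 0.79 (SE 0.15, adjusted p = 0.014). The MHC class II and costimulation median was -0.65 (adjusted p = 0.28), with 1 rise and 7 falls under the block. That median was -0.92 within replicates 1 and 2 (8 lower genes and 2 higher, adjusted p = 5.6e-13) and -0.28 within 3 and 4 (adjusted p = 0.52). Such within-batch list p-values set list genes against other genes and do not measure the spread between the 2 libraries per group. Pdia3 and Pdia4 fell by 0.47 and 0.46 (SE 0.08 and 0.11, adjusted p = 0.0087 and 0.042), with an unfolded protein response median of -0.09 (adjusted p = 0.12), 0.06 and -0.32 within the batches (adjusted p = 0.15 and 0.025). Kdm5b rose by 0.35 (SE 0.06, adjusted p = 0.012) among the 2-oxoglutarate-dependent dioxygenases, whose median was -0.02 (adjusted p = 0.71 in the upward direction). NRF2 targets had a median of 0.32 (adjusted p = 0.25; 0.21, adjusted p = 0.045 with the block, adjusted p = 0.84 with an estimated correlation and the block), 0.09 within replicates 1 and 2 and 0.45 within 3 and 4. Medians were -0.03 for the tricarboxylic acid cycle (adjusted p = 0.87), -0.05 for oxidative phosphorylation (adjusted p = 0.87) and 0.04 for fatty acid oxidation (adjusted p = 0.28).

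Markers of other cell types bear on what was sampled. Macrophage identity genes had a median of 0.01 and a mean of -0.03 (11 genes, adjusted p = 0.94). Dendritic, neutrophil, mast cell and lymphocyte marker medians were -0.13, 0.04, 1.23 and -0.78 (3, 3, 2 and 1 genes, adjusted p = 0.87, 0.93, 0.53 and 0.47); the neutrophil mean was -0.04. No erythroid marker had enough counts to test. Fewer stromal cells and lower expression in them were not separated here, and the simulated 1.5-fold changes were recovered in 36.4% of genes without the block.

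What AKG did in cells without glutamine was the next question (4 libraries each). edgeR's quasi-likelihood test called 186 genes (80 higher and 106 lower with AKG), and 1917 with the replicate block (1039 higher, 878 lower), among them all 186. Of the 186, 16 rose and 23 fell by more than 1 log2 unit (208 and 93 with the block). Values did not overlap in 1137 genes (9.10%), against 2.86% by chance if the batch is ignored.

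Several rises were in interferon response genes, a group that in resting macrophages depends on tonic type I interferon. Ifit3 (chr19:34583531-34588731, plus strand) rose from 101 to 252 CPM, a log2 fold change of 1.33 (SE 0.22, adjusted p = 0.020). Its neighbour Ifit3b (chr19:34607970-34613401, plus strand), close in sequence, rose by 1.49 (SE 0.28, adjusted p = 0.030). Isg15 rose by 1.10 (SE 0.21, adjusted p = 0.035), Ifit1 by 1.09 (SE 0.19, adjusted p = 0.025), Cmpk2 by 1.07 (SE 0.23, adjusted p = 0.046) and Oasl2 by 0.65 (SE 0.11, adjusted p = 0.024). Of 30 genes 12 rose (27 adjusted over the list alone; 28 with the replicate block) and 0 fell. The median was 0.84 (adjusted p = 4.9e-39, adjusted p = 0.13 with an estimated correlation), 1.06 within replicates 1 and 2 and 0.69 within 3 and 4. Macrophage identity markers moved less, with a median of 0.12 (adjusted p = 0.12).

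Further rises were Ctla2b (chr13:60895350-60897447, minus strand; 1.01, SE 0.06, adjusted p = 4.2e-05), Hpgd (1.20, SE 0.16, adjusted p = 0.0063), Lrrc4 (1.44, SE 0.31, adjusted p = 0.049), Phf11d (1.03, SE 0.21, adjusted p = 0.042) and Fam72a (1.06, SE 0.20, adjusted p = 0.032). Arg1, a gene of alternative activation, went from 2.16 to 7.66 CPM (1.83, SE 0.42, adjusted p = 0.062; 0.0019 with the replicate block). Its within-batch values were 1.47 in replicates 1 and 2 and 2.05 in 3 and 4. Mrc1 had 0.82 (SE 0.54, adjusted p = 0.60; 0.97, adjusted p = 0.0030 with the block). The IL-4 list did not pass, with a median of -0.26, a mean of 0.11 and a downward test (adjusted p = 0.77; 0.69 and upward with the block).

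Some antimicrobial genes fell with AKG. Clec4e fell by 1.32 (SE 0.18, adjusted p = 0.0072), Slpi (chr2:164354070-164389095, minus strand) by 1.69 (SE 0.26, adjusted p = 0.015) and F10 by 1.64 (SE 0.25, adjusted p = 0.016). Of 14 genes 3 fell (4 adjusted over the list alone; 1 rose and 5 fell with the replicate block), median -0.59 (adjusted p = 1.4e-06, adjusted p = 0.11 with an estimated correlation). In the inflammatory list Il6 fell by 3.43 (SE 0.71, adjusted p = 0.042), 1 of 22 genes (5 adjusted over the list alone; 3 rose and 5 fell with the block). Cxcl1 and Il1a had -1.82 and -2.04 (SE 0.42 and 0.47, adjusted p = 0.059 and 0.060; 0.013 and 0.022 with the block). The median was -0.37 (adjusted p = 0.017; 0.24 with the replicate block, adjusted p = 0.52 with an estimated correlation), -0.21 within replicates 1 and 2 and -0.33 within 3 and 4. Tnf had -0.40 (SE 0.49, adjusted p = 0.82) and Il1b -0.70 (SE 0.80, adjusted p = 0.81).

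Amino acid response lists had medians below 0. Trib3 had -1.47 (SE 0.37, adjusted p = 0.080; 0.0054 with the replicate block) and Asns -0.82 (SE 0.43, adjusted p = 0.47; 0.047 with the block). No ATF4 list gene was called (1 rose and 1 fell adjusted over the list alone; 1 rose and 9 fell with the block), and the median was -0.22 (25 genes, adjusted p = 0.0027, adjusted p = 0.68 with an estimated correlation), -0.48 within replicates 1 and 2 and -0.0067 within 3 and 4. For aminoacyl-tRNA synthetases 0 of 20 were called (5 fell adjusted over the list alone; 9 with the block), median -0.14 (adjusted p = 0.00050, adjusted p = 0.68 with an estimated correlation), -0.16 and -0.13 within the batches. Glul rose by 0.42 (SE 0.08, adjusted p = 0.030) and Slc38a1 fell by 0.46 (SE 0.08, adjusted p = 0.020). The glutamine use median was -0.15 (17 genes, adjusted p = 0.017; 0.066 with the replicate block, adjusted p = 0.52 with an estimated correlation; 1 rose and 4 fell with the block).

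NRF2 targets had a median of -0.62 with 0 of 12 called (adjusted p = 0.0061, adjusted p = 0.68 with an estimated correlation; 7 fell with the replicate block). Within-batch medians were -0.91 in replicates 1 and 2 and -0.51 in 3 and 4. Other falls were Slc43a3 (-2.09, SE 0.34, adjusted p = 0.018), Vwf (-1.58, SE 0.30, adjusted p = 0.032), C77080 (-1.40, SE 0.19, adjusted p = 0.0082), Cd33 (-1.39, SE 0.22, adjusted p = 0.015), Acsl1 (-1.30, SE 0.27, adjusted p = 0.042), Mt2 (-1.30, SE 0.15, adjusted p = 0.0061) and Bhlhe41 (-1.22, SE 0.18, adjusted p = 0.013). Bnip3 rose by 0.57 (SE 0.11, adjusted p = 0.031) in the glycolysis and hypoxia list (median 0.15, adjusted p = 0.070). That median was 0.06 within replicates 1 and 2 (camera adjusted p = 0.79, a downward test) and 0.24 within 3 and 4 (camera adjusted p = 0.00092). Mcoln1 and Atp6v0d1 fell by 0.34 and 0.35 (SE 0.06 and 0.07, adjusted p = 0.021 and 0.030), with a lysosome median of -0.06 (adjusted p = 0.070). Tollip fell by 0.35 and Ptpn6 rose by 0.35 (SE 0.07 each, adjusted p = 0.035 each); the negative regulators had a median of -0.01 and a mean of 0.00 (adjusted p = 0.41).

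Stromal markers had a median of 0.90 with 0 of 8 called (adjusted p = 0.070; 1.03, 6 rises and adjusted p = 5.3e-10 with the replicate block, adjusted p = 0.19 with an estimated correlation and the block). Within batches it was 1.25 in replicates 1 and 2 and 0.81 in 3 and 4. Cell cycle genes had 0.09 with 0 of 22 called (adjusted p = 0.34). Lists with no call had medians of -0.06 for the tricarboxylic acid cycle (adjusted p = 0.24), -0.05 for oxidative phosphorylation (0.12), -0.03 for fatty acid oxidation (0.24) and 0.09 for dioxygenases (0.15). Cholesterol synthesis gave -0.16 (0.12), MHC class II 0.45 (0.24) and the unfolded protein response 0.05 (0.34). Within replicates 1 and 2 cholesterol synthesis had -0.37 with 11 lower genes (adjusted p = 0.00012) and MHC class II 0.62 with 8 higher genes (adjusted p = 7.7e-10), and within 3 and 4 they had 0.05 and 0.16 (adjusted p = 0.73 and 0.68). Dendritic markers had a median of -0.27 with an upward test (0.77), neutrophil markers -0.74 (0.25), mast cell markers -0.60 (0.46) and lymphocyte markers 0.78 (0.32). The count of changed genes dropped to 28 without AKG replicate 2, to 32 without replicate 2 of the group without glutamine, and to 51 and 55 without AKG replicates 3 and 4.

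How far AKG opposed the changes seen without glutamine was counted gene by gene. Of the 587 genes 127 (21.6%, 95% interval 18.4 to 25.2%) changed in the opposite direction with AKG, 93 from higher to lower and 34 from lower to higher. The AKG calls held 0 in the same direction, and independent lists would share 4.36. With the replicate block 1287 of 2707 (47.5%, interval 45.6 to 49.4%) were opposed, against 211 expected, and 4 moved the same way. Both intervals are binomial and treat genes as independent, so they do not measure the spread between libraries. Clec4e, F10, Acsl1, Vwf, Slc43a3, Il6, Glul and Slc38a1 were among those opposed without the block, and stromal markers were not. With the block most stromal markers were opposed too, falling without glutamine and rising with AKG.

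Both fold changes share the libraries without glutamine, which alone makes them oppose each other. Their correlation over all genes was -0.744, and -0.501 in simulated counts with no effect of either treatment. The covariance was -0.169 against -0.0599 in the simulation, a difference of -0.109. With the replicate block the covariance was -0.170 against -0.0170 in its simulation. No simulated draw of 20 gave an opposed gene that passed both tests. Those draws called at most 1 gene without glutamine, so this was fixed by their setting and does not bear on the called genes. The shared libraries were also split, so that replicates 1 and 3 served for 1 comparison and 2 and 4 for the other. With the replicate batch as a factor, 793 of 2156 genes (36.8%) and 817 of 2346 (34.8%) were opposed, against 131 and 116 expected. Without the batch as a factor, 6 splits called only 21 to 354 genes and gave 1.52 to 52.4%, with r = -0.0064 where replicates 1 and 2 served for glutamine withdrawal. Leaving out 1 library moved the share of without Gln changes opposed by AKG to between 5.29 and 24.2%, so its size is uncertain. Opposed genes are therefore reported as a count and not as a shared cause.

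**Figure D3:**
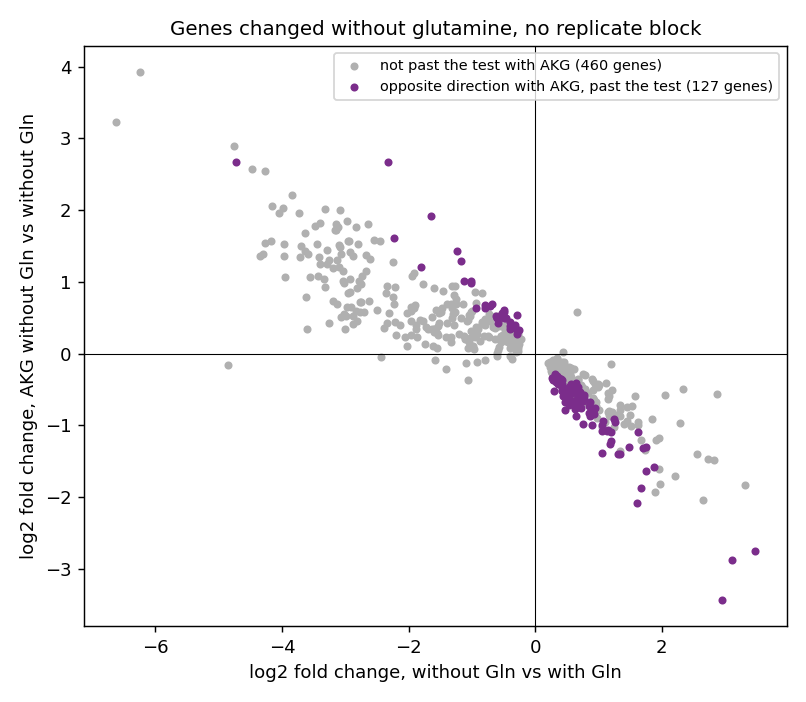
Log2 fold changes of the 587 genes changed without glutamine (horizontal) and their change with AKG (vertical), 4 libraries per group. Purple points are the 127 opposed genes that passed both tests; over all genes, simulated counts without any effect gave r = -0.501.

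What remained different from cells with glutamine once AKG was given was tested directly (4 libraries each). edgeR's quasi-likelihood test called 0 of 12492 genes, with a smallest adjusted p of 0.072 and 916 genes at an unadjusted p under 0.05. DESeq2 called 232 and limma-voom 0. The replicate block gave 876 genes (204 higher, 672 lower), so 0 calls without it do not show that the 2 groups were alike. Values did not overlap in 696 genes (5.57%), against 2.86% by chance if the batch is ignored.

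The interferon list had a median above 0, without a called gene unless the block was used. Rsad2 had 1.24 (SE 0.27, adjusted p = 0.17; 1.27, adjusted p = 0.00033 with the replicate block), Usp18 0.73 (SE 0.14, adjusted p = 0.14; 0.0072 with the block) and Cmpk2 1.02 (SE 0.23, adjusted p = 0.18; 0.0028 with the block). None of 30 was called (17 rose adjusted over the list alone; 22 with the block). The median was 0.60 (adjusted p = 1.7e-39, adjusted p = 0.077 with an estimated correlation), 0.56 within replicates 1 and 2 and 0.79 within 3 and 4. Arg1 had 1.76 (SE 0.42, adjusted p = 0.20; 1.82, adjusted p = 0.0023 with the block), while the IL-4 list median was 0.03 (adjusted p = 0.76). Glycolysis and hypoxia genes, which hypoxia-inducible factors drive and AKG-dependent prolyl hydroxylases restrain, had a median of 0.28 (21 genes, adjusted p = 3.1e-15, adjusted p = 0.077 with an estimated correlation). None passed over all genes, 4 rose adjusted over the list alone and 5 with the block, among them Bnip3 (0.68, SE 0.11, adjusted p = 0.075; 0.0046 with the block) and Egln3 (1.72, SE 0.35, adjusted p = 0.16; 0.0097 with the block).

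The stromal and cell cycle lists had medians below 0, without a called gene unless the block was used. Col1a1 had -2.98 (SE 0.81, adjusted p = 0.24; -2.75, adjusted p = 0.00026 with the replicate block), and the stromal median was -2.07 (8 genes, adjusted p = 4.0e-08, adjusted p = 0.22 with an estimated correlation, 0.010 with that and the block). None of these passed over all genes, 3 fell adjusted over the list alone and 7 with the block. Within batches it was -1.68 in replicates 1 and 2 and -2.0 in 3 and 4. Plk1 had -2.56 (SE 0.47, adjusted p = 0.14; 0.0011 with the block) and Cdc20 -1.66 (SE 0.27, adjusted p = 0.085; 0.0010 with the block). The cell cycle median was -0.84 (22 genes, adjusted p = 2.2e-28, adjusted p = 0.077 with an estimated correlation). Of its genes 16 fell adjusted over the list alone and 13 with the block; within-batch medians were -0.48 and -1.21. Cholesterol synthesis genes had -0.41 (21 genes, adjusted p = 2.3e-14, adjusted p = 0.14 with an estimated correlation), with 9 lower genes under the block, Idi1 at -1.26 (SE 0.30, adjusted p = 0.20; 0.021 with the block).

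Amino acid response genes had 0 calls without the block, and some were higher with it. Ddit3 had 0.71 (SE 0.13, adjusted p = 0.14; 0.011 with the replicate block), Trib3 1.26 (SE 0.37, adjusted p = 0.29; 0.022 with the block) and Asns 0.38 (SE 0.43, adjusted p = 1.0). The ATF4 median was 0.09 (adjusted p = 0.045; 0.20 with the replicate block, adjusted p = 0.82 with an estimated correlation; 3 rose and 1 fell with the block). Synthetases had 0.03 (adjusted p = 0.27) and glutamine use genes -0.05 (adjusted p = 0.058), with Glul at -0.16 (SE 0.08, adjusted p = 0.77). Inflammatory genes had a median of 0.31 (adjusted p = 0.038, adjusted p = 0.35 with an estimated correlation), 0.44 within replicates 1 and 2 and -0.01 within 3 and 4. Tnf had 0.03 (SE 0.49), Il1b 0.41 (SE 0.80), Il6 -0.48 (SE 0.72) and Mrc1 -0.25 (SE 0.54), each with adjusted p = 1.0. Acod1 had 0.80 (SE 0.23, adjusted p = 0.27), and its difference depended on the batch (interaction adjusted p = 0.043).

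Negative regulators of TLR signalling had a median of 0.21 (adjusted p = 1.0e-05, adjusted p = 0.22 with an estimated correlation), and antimicrobial genes 0.38 (adjusted p = 0.14), 0.64 within replicates 1 and 2 (adjusted p = 2.3e-11) and -0.13 within 3 and 4 (adjusted p = 0.39). Smaller shifts were 0.06 for dioxygenases (adjusted p = 0.0049, adjusted p = 0.22 with an estimated correlation; 2 rose with the block), -0.08 for the tricarboxylic acid cycle (adjusted p = 0.045; 0.29 with the replicate block, adjusted p = 0.39 with an estimated correlation) and -0.07 for oxidative phosphorylation (adjusted p = 0.013; 0.24 with the replicate block, adjusted p = 0.49 with an estimated correlation). Macrophage markers had 0.09 (adjusted p = 0.045; 0.051 with the replicate block, adjusted p = 0.49 with an estimated correlation). NRF2 targets had -0.24 (adjusted p = 0.089; -0.36, adjusted p = 0.0011 with the block, adjusted p = 0.55 with an estimated correlation and the block), -0.66 within replicates 1 and 2 and -0.05 within 3 and 4. Fatty acid oxidation had a median of -0.01 and a mean of 0.02 (adjusted p = 0.87), lysosome genes 0.01 (0.68), MHC class II genes -0.21 (0.88) and the unfolded protein response -0.07 (0.20). Dendritic, neutrophil, mast cell and lymphocyte markers had -0.39, -0.24, 0.63 and 0.01 (adjusted p = 0.95, 0.18, 0.87 and 0.97), the dendritic test being upward against its median.

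Genes set by IL-4 or LPS in the stimulation set were then followed in the tolerant set. The rule took the 50 genes with the smallest p induced by 1 stimulus and higher than under the other, of which 45 (IL-4) and 49 (LPS) were tested. LPS-induced genes had a median of 0.19 without against with glutamine (camera adjusted p = 0.00014, adjusted p = 0.14 with an estimated correlation). Only 26 of 49 lay above 0 (25 with the replicate block), so a part of the list and not the whole was higher. Called were 8 up and 1 down (12 and 1 adjusted over the list alone, 17 and 6 with the block). IL-4-induced genes had a median of -0.07 with 4 down (adjusted p = 0.033; 0.097 and 9 down with the replicate block, adjusted p = 0.14 with an estimated correlation). With AKG against no AKG neither list passed. LPS-induced genes had a median of -0.05 and a mean of 0.12 (adjusted p = 0.50), with 7 up and 3 down (13 and 10 adjusted over the list alone; 17 and 11 with the block). IL-4-induced genes had a median of -0.04 and a mean of 0.08 (adjusted p = 0.50), with 1 up (2 adjusted over the list alone; 8 up and 3 down with the block). AKG without glutamine against glutamine gave 0.42 for LPS-induced genes, 39 of 49 above 0 (adjusted p = 3.9e-14, adjusted p = 0.022 with an estimated correlation, 0.067 with that and the block; 14 up and 2 down with the block). The IL-4-induced median there was -0.12 (adjusted p = 0.014; 0.077 with the replicate block, adjusted p = 0.10 with an estimated correlation). The LPS-induced list holds 9 interferon response genes, 7 antimicrobial genes, 5 inflammatory genes, 2 negative regulators and 1 fatty acid oxidation gene, so it is not separate from those lists.

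The stimulation set asked what IL-4 does to untreated macrophages in 6 h, with 2 libraries per group. edgeR's quasi-likelihood test called 2518 of 12506 genes (1208 higher, 1310 lower), 636 and 524 of them by more than 1 log2 unit. Values did not overlap in 7288 genes (58.3%), against 33.3% by chance. In a simulated set of this size 45.5% of 2-fold changes were recovered, and 12% of its calls were false. Far fewer genes changed in it than were called here, so 12% is not the false share of these calls.

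IL-4 acts through STAT6, and its known targets led. Retnla (chr16:48842551-48844461, plus strand) had 90.3 CPM with IL-4 and 0 counts without, at least 2552-fold (adjusted p = 0.00015). Scn3a and Msx3 also had 0 counts without IL-4 and rose at least 1993-fold and 924-fold (adjusted p = 0.0025 and 0.00035). These bounds and the count-ratio intervals given later cover counting error only. Arg1 (chr10:24915221-24927484, minus strand) rose from 2.73 to 1117 CPM (8.67, SE 0.23, adjusted p = 4.2e-05), Pdcd1lg2 by 8.59 (SE 0.20, adjusted p = 4.2e-05), Cdh1 by 7.88 (SE 0.21, adjusted p = 4.2e-05), Chil3 by 5.36 (SE 0.17, adjusted p = 6.8e-05) and Mrc1 by 3.60 (SE 0.23, adjusted p = 0.00043). In the IL-4 list 22 of 24 genes rose (23 adjusted over the list alone), median 3.66 (adjusted p = 1.4e-40, adjusted p = 0.022 with an estimated correlation). That median was the same with the genes at 0 counts set to their bound.

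Other large rises were Cish by 6.87 (SE 0.65, adjusted p = 0.0033), Socs1 by 6.82 (SE 0.44, adjusted p = 0.00093), Socs2 by 5.42 (SE 0.16, adjusted p = 5.4e-05), Rasgrp1 by 8.66 (SE 0.25, adjusted p = 5.4e-05) and B3gnt7 by 6.04 (SE 0.16, adjusted p = 4.2e-05). Interferon response genes fell, 15 of 31 with 2 rises (17 and 2 adjusted over the list alone). Ifit3 fell by 2.44 (SE 0.11, adjusted p = 0.00016), Ifit1 by 2.11 (SE 0.14, adjusted p = 0.00049) and Ifit3b by 2.90 (SE 0.17, adjusted p = 0.00037), while Irf1 rose by 1.72 (SE 0.11, adjusted p = 0.00049). The median was -0.79 (adjusted p = 0.00019, adjusted p = 0.51 with an estimated correlation), or -0.44 with Ifnb1 (chosen after its values were seen), at 0 counts with IL-4, set to no change. Antimicrobial genes had -0.77 with 1 rise and 5 falls of 14 (2 and 8 adjusted over the list alone, adjusted p = 0.0061, adjusted p = 0.49 with an estimated correlation). Clec4d fell by 2.50 (SE 0.09, adjusted p = 0.00010) and Clec4e by 1.99 (SE 0.10, adjusted p = 0.00025), but F10 rose by 4.15 (SE 0.19, adjusted p = 0.00016).

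Cytokine genes split: Ccl7 rose by 4.48 (SE 0.23, adjusted p = 0.00025), Cd40 by 3.25 (SE 0.20, adjusted p = 0.00041) and Ccl2 by 2.92 (SE 0.13, adjusted p = 0.00017), and Tnf fell by 0.81 (SE 0.14, adjusted p = 0.012). Il1b had -0.62 (SE 0.25, adjusted p = 0.16), and Il6 had 2 counts in each group, a count ratio of 1.01 (interval 0.0735 to 14). The inflammatory median was 0.04, with 6 rises and 5 falls of 24 (adjusted p = 0.17). Cx3cr1 fell by 4.70 (SE 0.12, adjusted p = 4.2e-05), Fpr1 by 4.28 (SE 0.26, adjusted p = 0.00038), Trim30b by 4.12 (SE 0.49, adjusted p = 0.0033), Nfkbiz by 3.62 (SE 0.26, adjusted p = 0.00077) and Cgnl1 by 2.77 (SE 0.18, adjusted p = 0.00049). Mir155hg had 0 counts with IL-4 and was at least 4.93-fold lower (adjusted p = 0.014). Negative regulators had a median of -0.27 and a mean of 0.01 (adjusted p = 0.41), with Cd274 up by 2.51 (SE 0.16, adjusted p = 0.00046) and Irak3 down by 1.74 (SE 0.10, adjusted p = 0.00030).

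Antigen presentation genes rose: Cd86 by 1.81 (SE 0.10, adjusted p = 0.00030) and H2-DMa by 1.64 (SE 0.17, adjusted p = 0.0021), with 6 rises and 1 fall of 11 and a median of 0.58 (adjusted p = 0.013, adjusted p = 0.54 with an estimated correlation). ATF4 targets had 0.23 with 6 rises of 24, Atf5 at 1.25 (SE 0.11, adjusted p = 0.00096) (list adjusted p = 0.015, adjusted p = 0.54 with an estimated correlation). In the unfolded protein response list Pdia4 rose by 2.96 (SE 0.10, adjusted p = 7.3e-05), 3 rises and 1 fall of 17, median 0.24 (adjusted p = 0.043, adjusted p = 0.51 with an estimated correlation). NRF2 targets fell, 6 of 12 (9 adjusted over the list alone), median -0.49 (adjusted p = 0.0023, adjusted p = 0.54 with an estimated correlation), with Gsr down by 1.20 (SE 0.13, adjusted p = 0.0022). Glycolysis and hypoxia genes had -0.28 with 1 rise and 4 falls of 21, Vegfa at -1.51 (SE 0.10, adjusted p = 0.00049) (list adjusted p = 0.032, adjusted p = 0.72 with an estimated correlation).

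Glul had -0.08 (SE 0.11, adjusted p = 0.70) and Asns -0.13 (SE 0.12, adjusted p = 0.56), and glutamine use genes a median of 0.07 (adjusted p = 0.64). Dendritic markers had 3.01 with 3 rises of 5 (adjusted p = 0.0011, adjusted p = 0.38 with an estimated correlation), among them Itgax at 3.01 (SE 0.17, adjusted p = 0.00032). Neutrophil markers had -0.86 with 2 falls of 5 (3 adjusted over the list alone, adjusted p = 0.043, adjusted p = 0.51 with an estimated correlation). Lists that did not pass were synthetases (median 0.10, adjusted p = 0.099), tricarboxylic acid cycle (0.12, 0.18), oxidative phosphorylation (0.18, 0.079), fatty acid oxidation (-0.05, 0.92), dioxygenases (0.02, 0.64) and cholesterol synthesis (-0.16, 0.38). Cell cycle (-0.36, 0.16), lysosome (-0.23, 0.099), macrophage (-0.12, 0.11), mast cell (0.90, 0.14), lymphocyte (0.15, 0.82) and stromal genes (-0.48, 0.089) did not pass either. Without IL4_6h replicate 1 or 2, which leaves that group 1 library, the count was 944 or 972.

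The same question for LPS gave the widest response (2 libraries each). edgeR's quasi-likelihood test called 6519 genes (2856 higher, 3663 lower), 1407 and 2053 of them by more than 1 log2 unit. Values did not overlap in 9323 genes (74.5%), against 33.3% by chance. The scaling matters at this breadth: the median over all genes was -0.10 with TMM and 0.00 with RLE factors, so changes near that size were not interpreted. RLE factors gave 3201 higher and 3202 lower genes and DESeq2 gave 3231 and 3041, so the excess of lower genes depends on the scaling.

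LPS signals through TLR4 to NF-κB and interferon. Saa3 (chr7:46711998-46715700, minus strand) rose from 9.65 to 6760 CPM (9.45, SE 0.27, adjusted p = 2.6e-05), Nos2 (chr11:78920787-78960254, plus strand) by 11.15 (SE 0.63, adjusted p = 0.00021) and Il1b by 8.4 (SE 0.31, adjusted p = 3.2e-05). Tnf rose by 4.58 (SE 0.16, adjusted p = 2.6e-05), Acod1 by 8.48 (SE 0.20, adjusted p = 2.6e-05) and Il1a by 9.52 (SE 0.55, adjusted p = 0.00021). Il6 rose from 2 counts in the untreated group, a count ratio of 202 (interval 55.4 to 1677, adjusted p = 0.00052). Of 24 inflammatory genes 23 rose and 1 fell, median 5.47 (adjusted p = 5.4e-19, adjusted p = 0.25 with an estimated correlation). All 31 interferon genes rose, median 3.88 (adjusted p = 4.3e-29, adjusted p = 0.24 with an estimated correlation), with Gbp2 up by 6.05 (SE 0.19, adjusted p = 2.6e-05) and Ifit3 by 3.60 (SE 0.11, adjusted p = 2.6e-05). All 14 antimicrobial genes rose, median 5.47 (adjusted p = 2.9e-17, adjusted p = 0.20 with an estimated correlation), with Clec4e up by 5.67 (SE 0.12, adjusted p = 2.6e-05) and Fpr1 by 6.56 (SE 0.19, adjusted p = 2.6e-05).

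**Figure D4:**
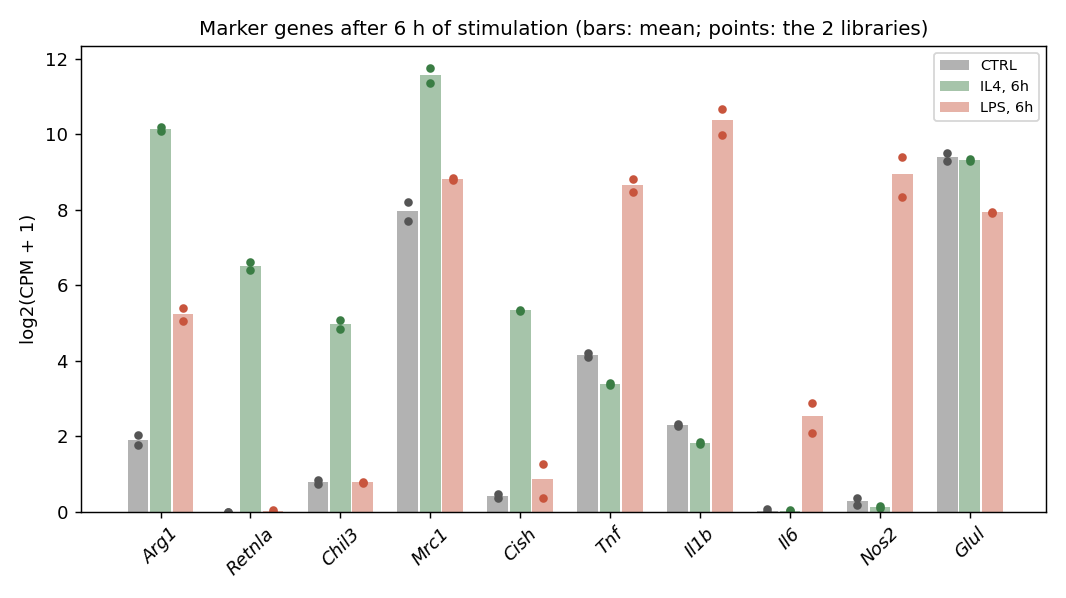
Marker gene levels as log2(CPM + 1) after 6 h; bars are group means and points the 2 libraries per group. Arg1, Retnla and Chil3 are highest with IL-4, and Tnf, Il1b, Il6 and Nos2 with LPS, while Glul is lowest with LPS.

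Brakes on TLR signalling rose with it, 21 of 23 genes, median 2.06 (adjusted p = 8.9e-15, adjusted p = 0.27 with an estimated correlation), with Socs3 up by 7.72 (SE 0.23, adjusted p = 2.6e-05) and Irak3 by 3.48 (SE 0.10, adjusted p = 2.6e-05). Steap4 had 0 counts without LPS and rose at least 459-fold (adjusted p = 0.00014), and U90926 and Shisa3 had count ratios of 1964 (interval 352 to 77612) and 779 (266 to 3784). Cd38, Ptges, Ifi205 and Cxcl11 rose by 9.49, 8.75, 8.69 and 8.65 (SE 0.17, 0.27, 0.33 and 0.30, adjusted p = 2.6e-05, 2.6e-05, 3.4e-05 and 2.7e-05). Rtn4rl1 had 0 counts with LPS and was at least 63.1-fold lower (adjusted p = 9.5e-05). Rasgrp3, Nptx1 and Gpr34 fell by 7.65, 6.58 and 6.2 (SE 0.69, 0.26 and 0.36, adjusted p = 0.00086, 3.0e-05 and 8.1e-05). Tlr5, Engase and Cnr2 fell by 5.84, 5.75 and 5.75 (SE 0.38, 0.26 and 0.19, adjusted p = 0.00012, 3.9e-05 and 2.6e-05). Tmem154, Abcd2 and E2f2 fell by 5.73, 5.69 and 5.62 (SE 0.16, 0.51 and 0.32, adjusted p = 2.6e-05, 0.00088 and 9.6e-05).

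Among glutamine use genes Glul fell from 670 to 242 CPM (-1.47, SE 0.11, adjusted p = 0.00017) and Got1 by 1.90 (SE 0.15, adjusted p = 0.00023). Of the 17 in that list 12 fell, median -0.71 (adjusted p = 0.0038, adjusted p = 0.25 with an estimated correlation). Glycolysis and hypoxia genes rose, 20 of 21 with 1 fall, median 1.54 (adjusted p = 4.6e-11, adjusted p = 0.32 with an estimated correlation), Pfkfb3 by 4.71 (SE 0.17, adjusted p = 2.7e-05). Cholesterol synthesis genes fell, 18 of 21 with 1 rise, median -1.14 (adjusted p = 1.4e-05, adjusted p = 0.25 with an estimated correlation), Dhcr7 by 3.72 (SE 0.18, adjusted p = 4.4e-05). Cell cycle genes fell, 14 of 22 with 1 rise, median -0.71 (adjusted p = 0.0050, adjusted p = 0.25 with an estimated correlation), Mcm7 by 2.13 (SE 0.13, adjusted p = 8.9e-05). ATF4 targets had 0.61 with 12 rises and 5 falls of 24 (adjusted p = 0.011, adjusted p = 0.59 with an estimated correlation), Slc7a11 up by 5.01 (SE 0.28, adjusted p = 9.5e-05) and Asns by 0.44 (SE 0.12, adjusted p = 0.026).

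NRF2 targets had 0.50 with 7 rises and 2 falls of 12 (adjusted p = 0.021, adjusted p = 0.61 with an estimated correlation), Gsr up by 3.0 (SE 0.13, adjusted p = 3.8e-05). Dioxygenases had 0.59 with 10 rises and 2 falls of 20 (adjusted p = 0.024, adjusted p = 0.25 with an estimated correlation), Egln1 up by 1.75 (SE 0.14, adjusted p = 0.00020). Acsl1 rose by 3.94 (SE 0.11, adjusted p = 2.6e-05), but 12 of 18 fatty acid oxidation genes fell and the median was -0.42 (adjusted p = 0.086). Idh2 fell by 1.37 (SE 0.12, adjusted p = 0.00035), while the tricarboxylic acid cycle median was 0.05 and its mean -0.02 (adjusted p = 0.94). Arg1 rose by 3.75 (SE 0.19, adjusted p = 5.7e-05) and Mrc1 by 0.85 (SE 0.21, adjusted p = 0.016), Chil3 had -0.04 (SE 0.20, adjusted p = 0.92), and the IL-4 list had 8 rises and 9 falls of 24 (median -0.02, mean 0.21, adjusted p = 0.94). Retnla had 1 count in the LPS group and 0 in the untreated one, which gives no bound.

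Among lists that did not pass were oxidative phosphorylation (median 0.22, adjusted p = 0.075), synthetases (0.16, 0.48), lysosome genes (-0.53, 0.12) and the unfolded protein response (0.08, 0.59). MHC class II genes had a median of 0.42 and a mean of -0.15 (0.63), with Ciita down by 2.69 (SE 0.17, adjusted p = 9.6e-05). Macrophage markers had 0.03 with 5 rises and 1 fall of 11 (0.23), Fcgr1 up by 2.61 (SE 0.13, adjusted p = 4.6e-05) and Mertk down by 2.76 (SE 0.27, adjusted p = 0.00071). Dendritic markers had 0.10 (0.35), neutrophil markers 0.17 (0.59), mast cell markers -0.31 (0.99) and lymphocyte markers -1.91 (0.41). Stromal markers had a median of -0.09, a mean of 0.12 and an upward test (0.66), and Pdgfrb rose by 1.15 (SE 0.19, adjusted p = 0.0037). Histone transcripts, a sign of dividing cells or of poly-A loss, were 0.00568% of counts with LPS and 0.0207% without.

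A direct comparison of IL-4 with LPS asked where the stimuli part. edgeR's quasi-likelihood test called 6641 genes (3714 higher with IL-4, 2927 higher with LPS), 2073 and 1560 by more than 1 log2 unit. That balance depends on the scaling too, with 3284 and 3156 for RLE factors and 3117 and 3213 for DESeq2. Values did not overlap in 10046 genes (80.3%), against 33.3% by chance. Irf4 was higher with IL-4 by 8.81 (SE 0.20, adjusted p = 9.8e-06), Arg1 by 4.92 (SE 0.19, adjusted p = 1.9e-05), Chil3 by 5.4 (SE 0.18, adjusted p = 1.4e-05), Mrc1 by 2.75 (SE 0.22, adjusted p = 0.00019) and Glul by 1.39 (SE 0.11, adjusted p = 0.00017). Msx3 and Rtn4rl1 had 0 counts with LPS and were at least 628-fold and 169-fold higher (adjusted p = 7.3e-05 and 4.0e-05). Retnla and Scn3a, at 1 count with LPS, had count ratios of 5210 (interval 935 to 205799) and 4068 (730 to 160720). Among genes lower with IL-4, Nos2 had -12.28 (SE 0.68, adjusted p = 0.00017), Ptges -10.88 (SE 0.29, adjusted p = 1.1e-05), Fpr1 -10.84 (SE 0.25, adjusted p = 9.8e-06) and Lipg -10.69 (SE 0.64, adjusted p = 0.00021). Mir155hg had 0 counts with IL-4, at least 606-fold lower (adjusted p = 4.3e-05). Tnf had -5.39 (SE 0.16, adjusted p = 1.2e-05), Il1b -9.02 (SE 0.32, adjusted p = 1.9e-05) and Asns -0.57 (SE 0.12, adjusted p = 0.010).

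Lists parted as strongly. IL-4 genes were higher, 21 of 24 with 2 lower, median 4.23 (adjusted p = 6.2e-15, adjusted p = 0.077 with an estimated correlation). Inflammatory genes were lower, 21 of 24 with 2 higher, median -4.94 (adjusted p = 2.6e-14, adjusted p = 0.32 with an estimated correlation). Interferon genes were lower, 30 of 31, median -4.16, or -3.99 with Ifnb1 (chosen after its values were seen) at its bound (adjusted p = 4.2e-28, adjusted p = 0.18 with an estimated correlation). Antimicrobial genes had -6.28, 13 of 14 lower (adjusted p = 3.4e-15, adjusted p = 0.077 with an estimated correlation), and negative regulators -2.52, 18 of 23 lower and 1 higher (adjusted p = 2.1e-12, adjusted p = 0.32 with an estimated correlation). Glycolysis and hypoxia genes had -1.79, all 21 lower (adjusted p = 3.9e-13, adjusted p = 0.32 with an estimated correlation), and NRF2 targets -0.86, 10 of 12 lower and 2 higher (adjusted p = 0.00053, adjusted p = 0.43 with an estimated correlation). Cholesterol genes had 0.90, 17 of 21 higher and 1 lower (adjusted p = 0.00032, adjusted p = 0.33 with an estimated correlation), and glutamine use genes 0.83, 11 of 17 higher and 1 lower (adjusted p = 0.0048, adjusted p = 0.27 with an estimated correlation).

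Elsewhere the contrast did not pass: ATF4 (-0.23, adjusted p = 0.33), synthetases (0.13, 0.78), tricarboxylic acid cycle (0.01, 0.57), oxidative phosphorylation (-0.04, 0.48), fatty acid oxidation (0.50, 0.098), dioxygenases (-0.53, 0.064), cell cycle (0.36, 0.11) and lysosome genes (0.10, 0.60). MHC class II (0.71, 0.34), unfolded protein response (0.01, 0.69), macrophage (-0.20, 0.12), dendritic (2.92, 0.34), neutrophil (-0.85, 0.099), mast cell (1.21, 0.33), lymphocyte (2.06, 0.34) and stromal markers (-0.43, 0.12) did not pass either.

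Genes that IL-4 and LPS both changed were counted by direction. Both raised 403 (276 expected of independent lists) and both lowered 663 (384 expected), 1066 in the same direction, while 755 moved in opposite directions (375 raised by IL-4 and lowered by LPS, 380 the reverse; 354 and 299 expected). The correlation of the fold changes was 0.109, against 0.487 in simulated counts with no effect, which share the untreated libraries; their covariance was 0.142 against 0.0463. Simulated draws gave a mean of 0.35 genes called in the same direction for both, but called at most 6 genes for IL-4, so few could be shared. The covariance exceeded the simulated one by 0.0952. With 1 untreated library given to each comparison, replicate 1 to IL-4 or replicate 2 to IL-4, 1077 and 993 genes moved in the same direction (712 and 673 expected of independent lists), and 815 and 808 in opposite directions (712 and 667 expected). The excess therefore stayed without a shared library, each lone library being assumed to vary like the other groups. It was present for the same and for opposite directions, so by itself it does not show a shared response.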

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

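Samples standing apart by Dixon's test are listed first. Each test took 1 measure in 1 group. Flagged were 0 of 18 tests of library measures, 3 of 75 of list scores and 6 of 129 of named genes. Chance gives about 1 in 20, so the flags are no more than chance would give. The fatty acid oxidation score of AKG replicate 4 was 5.46 log2 CPM, the nearest library 5.33. The lysosome score of replicate 3 without glutamine was 8.57, the nearest 8.42. That of AKG replicate 4 was 8.41, the nearest 8.33. Plcxd2 in AKG replicate 1 was 3.44, the nearest 1.81. Vwf in AKG replicate 1 was 5.22, the nearest 4.13. F10 in replicate 1 with glutamine was 1.92, the nearest 2.66. Slc43a3 in replicate 1 without glutamine was 3.10, the nearest 3.67. C77080 in AKG replicate 2 was 4.30, the nearest 5.25. Bhlhe41 in AKG replicate 2 was 4.55, the nearest 5.33.

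The tests of the next patterns were chosen after seeing the results, except the regrouped splits without the block. With the block there are 8 regroupings, too few for a share under 0.05. The tests of stromal genes, alone and against the cell cycle, were revised after their results were seen.

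Stromal markers were lower without glutamine. Fewer stromal cells as the only cause would lower all abundant members alike. Their falls differed (chi-square heterogeneity p = 1.2e-05, an approximate test that treats genes as independent), but this came from Col1a1 alone. With the block it changed by -4.24 (SE 0.23), against -2.89 to -3.43 for Col1a2, Sparc, Col5a1 and Col3a1. With Col1a1 left out the chi-square p = 0.10. Averaged within batches, AKG restored 10.9% of the fall of Col1a1 and 15.3% of that of the others. Without Col1a1 the member furthest from the rest, Col3a1, differed by -1.53 points (jackknife SE 0.794). So 1 gene departs from a common loss of cells, and fewer stromal cells stay open as the cause for the list. The batch is not the cause, since the within-batch median closest to 0 was -2.88. In a permutation of the labels 5 of 35 regroupings gave a result as large (real camera p = 1.2e-07, strongest other 8.3e-11). The strongest other kept 3 libraries without glutamine and had 1 library from replicates 3 and 4, so the batch adds to it. Without the block these regroupings therefore cannot decide about chance, which is not excluded. With the replicate block the list had camera adjusted p = 2.7e-42. There 1 of 8 regroupings in a permutation reached the real camera p = 1.1e-43 (strongest other 5.0e-07).

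Interferon response genes were higher with AKG than without glutamine. A larger share of macrophages would raise macrophage markers as much, but their median was 0.12 (SD 0.29) against 0.84. The batch does not explain it, since the smaller within-batch median was 0.69. In a permutation of the labels only the real 1 of 35 regroupings reached its value (real camera p = 1.9e-40, strongest other 1.1e-34). With the block 1 of 8 in a permutation did (real camera p = 5.0e-40, strongest other 2.3e-13).

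Cell cycle genes were lower without glutamine. If the cycling cells were the stromal ones, the AKG libraries would follow the stromal score; they lay -0.088 (SE 0.017) from the prediction, against a predicted rise of 0.25. Gene by gene on the CPM scale, over all libraries without regard to batch, AKG restored 8.29% of the fall in cell cycle genes (SD 12.2) and 12.2% in stromal genes (SD 13.6). Log2 medians lie further apart, at -1.07 without glutamine and 0.09 with AKG for cell cycle genes and -2.97 and 0.90 for stromal genes. The gene-by-gene shares differed by less than the spread between genes, so that test cannot decide. In the library test every AKG library lay below the prediction but above the level without glutamine. The libraries thus followed the stromal prediction in direction but not in full size, and the explanation stays undecided. The within-batch median closest to 0 was -0.45. In a permutation of the labels 3 of 35 regroupings gave a result as large (real camera p = 2.7e-16, strongest other 6.4e-19), so chance is not excluded here either. With the block 3 of 8 in a permutation did (real camera p = 7.5e-11, strongest other 1.1e-12; list adjusted p = 9.3e-10).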

How the results depend on the processing

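Some of these tests were added after seeing the data: the batch as a factor, each batch alone, the crossed block and the split of untreated libraries. Counts of changed genes depended on the fit. Glutamine withdrawal gave 1260 with DESeq2, 243 with the 2 groups alone, 2707 with the replicate block, 3090 with the batch as a factor, 3526 in replicates 1 and 2 and 1670 in 3 and 4. AKG against no AKG gave 123 without a filter, 682 with DESeq2, 60 with the 2 groups alone, 1917 with the block, 2312 with the batch, 2908 in replicates 1 and 2 and 703 in 3 and 4. AKG against glutamine gave 232, 876, 1133, 1433 and 790 with DESeq2, the block, the batch, replicates 1 and 2, and 3 and 4. The opposed share was 16.2% without a filter, 25.9% at 1 CPM, 33.6% with DESeq2, 28.8% with limma-voom, 47.5% with the block, 50.3% with the batch, 52.4% in replicates 1 and 2 and 29.5% in 3 and 4. Splits of the libraries without glutamine gave 15.5, 7.34, 36.4, 1.52, 52.4 and 8.11%, and with the batch 36.8, 34.8, 39.1 and 31.4%. The cause was not tested.

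Transferred medians no longer passed for IL-4-induced genes without glutamine (-0.066 with an estimated correlation, -0.14 with the replicate block, -0.12 for lists of 20, -0.13 for all genes), for LPS-induced genes (0.19 estimated, 0.0038 for all genes), and for IL-4-induced genes with AKG against glutamine (-0.12, -0.11 with the block, -0.093 for lists of 20). LPS-induced genes with AKG against no AKG reversed to -0.35 in lists of 20 and passed at 0.074 for all genes. Reversed within a batch, with at least 1 of the values past the test, were S100a8 (-0.93) and Itgax (-0.38) without glutamine, Il1b (-0.71) and the inflammatory list (-0.015) with AKG against glutamine, and the interferon list without glutamine (0.083). Antimicrobial genes with AKG against glutamine, not past the test in either fit, went from 0.38 to -0.13 in replicates 3 and 4. Estimated correlations ended 11 of 11 called lists without glutamine and 7 of 7 with AKG against no AKG. With AKG against glutamine they ended 12 of 12. Together with the block they ended 10, 7 and 11 of these. For IL-4, LPS and IL-4 against LPS they ended 9 of 10, 11 of 11 and 9 of 9. Of the called lists fry ended 8 of 11 without glutamine and 5 of 7 with AKG against no AKG. It ended 12 of 12 with AKG against glutamine, and added 0 in these comparisons. For IL-4 it ended 1 of 10 and added 5. For LPS it ended 0 of 11 and added 6, and for IL-4 against LPS 0 of 9 and 13. With the replicate block 30, 40 and 29 named genes gained a call in the 3 tolerant comparisons, and 0 lost one or reversed. Leaving out 1 library cost 26 of 48 named genes their call at least once for glutamine withdrawal (3 gained one). For AKG against no AKG it cost 24 of 30 (5 gained one). The 2 groups alone cost 22 and 15 (1 and 2 gained one), and limma-voom 11 and 3 (0 and 3 gained one).

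Leaving out 1 library gave 229 (without replicate 2 without glutamine) to 529 genes, 28 (without AKG replicate 2) to 158, and 0 to 0; the share of without Gln changes opposed by AKG ran from 5.29 to 24.2%. IL-4 gave 944 (without IL-4 replicate 1) to 2751, LPS 4574 to 6567, IL-4 against LPS 4662 to 7411, and genes changed by both IL4 and LPS 361 (without IL-4 replicate 1) to 1222, the lone sample being assumed to vary like other groups. The range for both stimuli counts only genes changed in the same direction, of which all libraries together gave 1066. In the stimulation set the replicate numbers did not pair the samples. There the block gave 1961, 6038 and 6100 genes, and a crossed block 3965, 7964 and 8023. The crossed block swaps the IL-4 replicate numbers, the pairing whose correlations in these same counts were all positive (0.66, 0.50 and 0.37). Such a pairing lowers the residual spread, so its higher counts are not independent support. With the crossed block both stimuli changed 1771 genes in the same direction. RLE factors ended 4 of 10 list calls for IL-4 and 1 of 11 for LPS, and added 0.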

Other observations

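The tests of regrouped libraries were planned before the counts were read; the blocked test of LPS-induced genes and the tests between batches were chosen after seeing the results. Of 35 regroupings, 2 gave as many changed genes as glutamine withdrawal (587), the highest other being 1637. For AKG against no AKG it was 2 (186, highest other 3748). For AKG against glutamine the real count was 0, which all 35 reach whatever the data, so this tests nothing (highest other 4561). In each case the split with the highest count follows the batch, and this points to sample structure; the remaining splits gave 0 genes. With the replicate block there are 8 regroupings, too few for a share under 0.05: real counts were 2707, 1917 and 876, and the highest others 0, 0 and 1, with 1 split as large in each. For LPS-induced genes higher with AKG than with glutamine, 3 of 35 regroupings in a permutation of the labels were as large (real camera p = 2.0e-14, strongest other 9.6e-17). With the block 2 of 8 in a permutation were (real camera p = 1.6e-13, strongest other 1.0e-16).

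The batches also differed in how the groups responded. Genes whose change differed between batches numbered 306 without glutamine, 7 with AKG against no AKG and 201 with AKG against glutamine. The fold changes in the batches correlated at 0.705, 0.583 and 0.522.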
